A study of Mus musculus with 49 samples.

How the data were processed

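Single neurons of the mouse somatosensory cortex were recorded and aspirated by the submitters, and their RNA was sequenced with a SMART-Seq kit that reads transcript ends, per the labels' protocols. The labels give for each of the 49 samples a radial position, and for most a membrane value (46 samples), a capacitance (46) and an Ih current (37). A missing value was left missing. The deposited table holds 49585 genes and 49 columns of CPM (reads per 1000000), which the authors had computed before deposit: each column sums to 1000000. STAR, HTSeq and the genome build GRCm38 are named in the submitters' processing notes. Their versions, the annotation release and the strand setting are not given in the sources used here, so reads of a gene and of an antisense partner cannot be told apart. 93 symbols occur on more than 1 gene identifier. Gene coordinates are from GENCODE annotation of the same build.

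The CPM values are whole multiples of what 1 read is worth in their column. 100% of values came out whole within a tolerance of 0.001, so the reads behind the CPM were recovered. They were 100363 to 6842382 per column (median 454404). In a library, 3 reads, the limit that a count of 0 allows, correspond to 0.242 CPM in the deepest and 11.8 CPM in the shallowest. The reads carry no molecular identifiers and are not independent molecules, so these floors cover counting error only.

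Columns were compared in pairs over genes with at least 20 reads, by the variance of the read division over its binomial variance. Pairs below 20 were treated as 1 library, and their mean CPM and summed reads were used. Applied to simulated columns, this step recovered 12 of 12 simulated pairs over 49585 genes. The simulated pairs differed by counting error alone. Their recovery therefore does not cover pairs as far apart as the real ones, with ratios of 2.24 to 8.05. Pairs joined pools 2 with 3 and pools 4 with 5, so the 5 pools became 3 pool sets. A library entered a zone comparison where its names lay in 1 zone (13 libraries), and the other 12 libraries entered none. This handling, the pool sets and the library numbers were chosen after the columns had been compared. The zones, gene lists, naming rule and planned tests had been fixed before the data were examined, and the main gene test was changed after that.

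The planned test was edgeR on counts summed over each pool and zone, and it was run on the recovered reads as an alternative. Because the values were CPM, the main test became limma with a mean-variance trend on log2(mean CPM + 1) over the 8 means of pool set and zone, with the pool set as a term (3 residual degrees of freedom). A fold change is therefore on the log2(value + 1) scale and understates the change of low genes. Genes passed the edgeR filter filterByExpr on the recovered reads. p-values were adjusted by the Benjamini-Hochberg method at 0.05, and tests were two-sided. Gene lists (26 fixed, 24 with at least 3 tested genes) were tested with camera at a preset correlation of 0.01 and at an estimated one, and with fry, in which none passed. The pool set was kept as a term because the titles mark shared library pools. Deviations of lower and upper means from the same set did not go together (correlations -0.01, -0.03 and 0.00).

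On data simulated for the comparison of upper and lower libraries with the libraries' own spread, 0% of genes changed 4-fold and 12% of genes changed 32-fold were called among 10892 genes tested, with 0 false calls. With a small spread 100% of both were called among 11463 genes, and 131 unchanged genes were called as well.

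Named genes were, per comparison, up to 8 in each direction. Those past the threshold came first by size, then those with the smallest p, said not to pass, with reads in at least 10 libraries and the same sign in every pool set. Gene models without a common name were skipped. The layer genes Cux2, Rorb, Pou3f2, Fezf2, Bcl11b, Tbr1, Foxp2 and Tle4, and Slc17a7 and Gad1, were always named, with the 4 list members of smallest p. Some genes that the rule names are not reported here, and no others took their place. The rule had been written for cells and 5 pools and was applied to libraries and pool sets. Genes given for single libraries were chosen after their values were seen.

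Recorded values were compared over the 49 samples by their labels, by exact sign-flip tests on within-pool differences of zone means. Slopes of genes on position, Ih, capacitance and the membrane value were planned and not run, since each library carried the values of 2 neurons. Alternatives covered scaling, filters, the pseudocount, zone limits, the count models edgeR and DESeq2, and leaving out pool sets or libraries. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and R 4.3.3 with limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0, were used.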

Results

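Neurons born on embryonic day 13.5 were examined in the primary somatosensory cortex of CD1 mice on postnatal day 7. Cells dividing at the ventricle on that embryonic day had been marked by FlashTag, a fluorescent dye injected into the ventricle. Each marked neuron was recorded by whole-cell patch clamp in a brain slice, and its cytoplasm was then drawn into the pipette for RNA sequencing. The 49 samples are 49 single neurons, for which the labels give a radial position between 0 at the white matter and 1 at the pia. The position ranged from 0.189 to 0.805, with a median of 0.436. With limits fixed before the data were examined, 20 neurons lay in the lower zone (below 0.4), 13 in the middle zone and 16 in the upper zone (from 0.55). The sample titles name 5 library pools of 9 to 12 neurons, and each pool held neurons of all 3 zones. No animal is named, so the pool was the replicate, and p-values measure the spread between pools, which may be technical.

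The first comparison asks whether neurons born together differ in their electrical properties with the position they reached. Neurons in the upper zone had a larger mean Ih current than those in the lower zone in 5 of 5 pools. Ih is the inward current carried by HCN channels on hyperpolarization. Its mean was 10.5 ± 5.57 pA (SD, n = 15 cells) in the lower zone, 19.1 ± 12.3 pA (n = 10 cells) in the middle zone and 17.0 ± 9.09 pA (n = 12 cells) in the upper zone. Membrane capacitance, a measure of membrane area, was 28.1 ± 12.5 pF (n = 19 cells) in the lower zone, 35.3 ± 19.3 pF (n = 13 cells) in the middle zone and 39.9 ± 20.3 pF (n = 14 cells) in the upper zone. It too was larger in the upper than in the lower zone in 5 of 5 pools. The value labelled membrane resistance, which the labels give in mV, averaged -55.2 ± 8.18 mV (n = 19 cells) in the lower zone, -56.6 ± 9.51 mV (n = 13 cells) in the middle zone and -58.3 ± 6.21 mV (n = 14 cells) in the upper zone. A resistance cannot be negative, so which quantity this value is stays unclear.

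Within pools, the upper zone exceeded the lower zone by 10.8 ± 9.11 pA for Ih (SD, n = 5 pools; two-sided exact sign-flip p = 0.0625, adjusted p = 0.0938 over the 3 measures). For capacitance the difference was 11.4 ± 11.7 pF (n = 5 pools, exact p = 0.0625, adjusted p = 0.0938), from 0.25 pF in pool 3 to 30.29 pF in pool 4. In pool 2 the upper mean, and in pool 4 the lower mean, came from a single neuron for both measures. These pools had the largest Ih differences, 22.09 pA in pool 2 and 19.12 pA in pool 4. The membrane value was lower in the upper zone in 4 of 5 pools, with a mean difference of -5.03 ± 3.51 mV (exact p = 0.125, adjusted p = 0.125). With 5 pools the smallest p that this exact test can give is 0.0625, so none of the 3 measures could pass a threshold of 0.05. The middle zone exceeded the lower zone by 9.85 ± 5.1 pA for Ih in 5 of 5 pools (exact p = 0.0625), while the upper and middle zones differed by 0.92 ± 8.16 pA (exact p = 0.875). The differences between upper and lower neurons depended on the limits of the zones. With neurons divided at a position of 0.45 into a lower and an upper group, they were 6.23 pA for Ih, 4.07 pF for capacitance and -0.23 mV for the membrane value. Without pool 4 the capacitance difference was 6.70 pF.

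**Figure D1:**
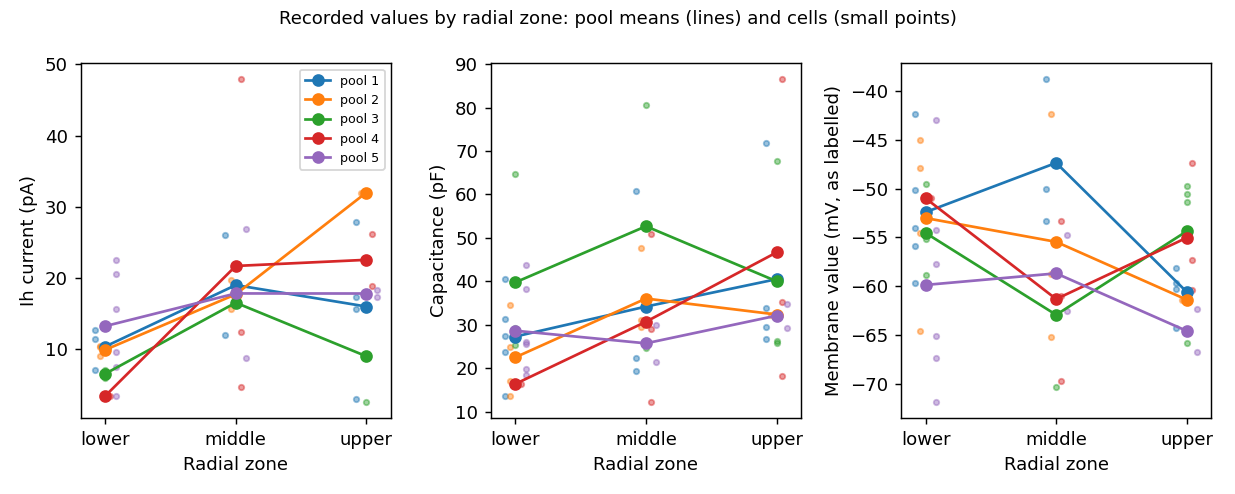
Ih current in pA, capacitance in pF and the membrane value in mV (vertical axes) by radial zone (horizontal axis). Small points are single neurons, and large points joined by lines are the means of the 5 pools. The upper mean lies above the lower mean in 5 of 5 pools for Ih and for capacitance.

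The expression table holds 49 columns, each named after 1 neuron, and these columns were not 49 separate libraries. 48 of them formed 24 adjacent pairs in which the 2 columns were far closer to each other than to any other column. The variance between the 2 columns of a pair was 2.24 to 8.05 times the counting variance, against 47.8 or more (median 96.5) for any other 2 columns. Of 79236 gene values with at least 50 reads in the first column, 137 (0.173%) were 0 in its partner, against 30.7% in a column of another library. The 2 columns of a pair were not identical, and they differed in the same genes from pair to pair. Ccnd3, which encodes cyclin D3, was lower in the second column in 24 of 24 pairs (median log2 ratio -4.68), as were Lipe (-4.12), Tmsb10 (-3.66) and Rpl38 (-2.56). Each pair was therefore counted as 1 library, which gave 25 libraries, numbered here from 1 to 25.

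Each of the 24 pairs carried the names of 2 different neurons. The 2 names lay in different radial zones in 12 pairs and in the same zone in the other 12. The pairs joined 2 names within pool 1 in 6 cases, names of pools 2 and 3 in 9 cases and names of pools 4 and 5 in 9 cases. Which neuron a library came from was therefore open, and no gene was related to the recorded current, capacitance or membrane value, or to position as a continuous number. The libraries held 254182 to 12419177 reads (median 858030), with 4121 to 14636 genes detected (median 7133).

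**Figure D2:**
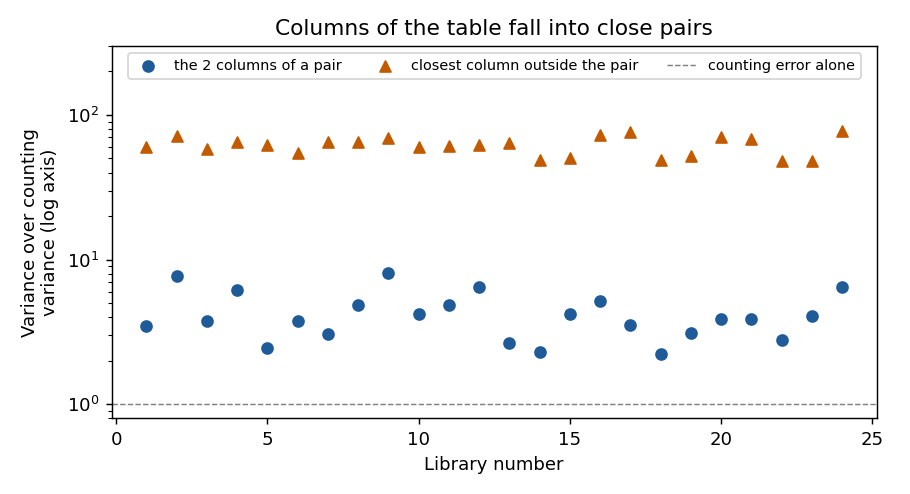
Variance between columns divided by the counting variance (vertical log axis) for the 24 libraries with 2 columns (horizontal axis). Circles compare the 2 columns of a pair, triangles compare a pair with the closest column outside it, and the dashed line marks counting error alone. The circles lie between 2.24 and 8.05, below every triangle.

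Several genes of young neurons were detected in each library. Gap43, which encodes a growth cone protein, Stmn2, Tubb3 and Dpysl3 were at or above 50 CPM (reads per 1000000) in 25 of 25 libraries. The calmodulin-binding gene Nrgn, listed here among excitatory genes, was also at that level in 25 of 25. Median levels were 1516 CPM for Gap43, 2759 CPM for Stmn2 and 1299 CPM for Nrgn. Other genes of young neurons were detected in fewer libraries, with Sox11 at that level in 14, Sox4 in 11 and Stmn1 in 2. At least 4 of the 10 listed excitatory genes reached 50 CPM in 14 of 25 libraries (56.0%, exact 95% interval 34.9 to 75.6%). Of that list, which includes Nrgn, the vesicular glutamate transporter gene Slc17a7 reached that level in 7 libraries, Neurod2 and Neurod6 in 12 each, and Camk2a in 12.

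Genes of other cell types were present, at high levels in single libraries, although the labels call every cell excitatory. At least 4 listed interneuron genes reached 50 CPM in 5 of 25 libraries (20%, exact 95% interval 6.8 to 40.7%). Library 10 had 558 CPM of Gad1, 806 CPM of Gad2 (the enzymes of GABA synthesis) and 3625 CPM of Npy, and library 21 had 9 of the 13 interneuron genes at that level against 1 of the 10 excitatory genes. Microglia genes reached it with 4 or more members in 5 libraries. Library 20 had 3371 CPM of Tyrobp, 2982 CPM of Aif1 and 2022 CPM of C1qb. Library 5 had 1995 CPM of Olig1 and 1408 CPM of Pdgfra, both genes of the oligodendrocyte lineage, whose list reached 4 members in 3 libraries. Astrocyte genes did so in 12 libraries, with Slc1a3 highest in library 17 (1121 CPM). Of that list Apoe, Clu, Sparcl1 and Slc1a2 were at or above 50 CPM in 17, 16, 18 and 13 libraries. Slc1a3 reached that level in 5, Gja1 in 3 and Gfap in 1. Common and rare members weigh alike in the count of 12, so it does not show astrocyte RNA in each of these libraries. The endothelial list reached 4 members in 1 library and the mural list in 0 of 25 (exact 95% interval 0 to 13.7%). Hemoglobin genes and Alas2 made up 69.0% of library 2, 21.8% of library 11, 11.8% of library 3 and 9.06% of library 24. In 6 libraries 4 or more of these 5 genes reached 50 CPM. Red cell transcripts were nonetheless general. Hbb-bs reached 50 CPM in 24 of 25 libraries (median 1025 CPM), and Hba-a1 and Hbb-bt did so in 20 each. These intervals treat the 25 libraries as independent draws and do not cover counting error within a library.

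Genes that mark the cortical layers overlapped within libraries. At 50 CPM, Cux2, Rorb, Pou3f2 and Bcl11b were each found in 11 of 25 libraries, Foxp2 in 7, and Fezf2, Tbr1 and Tle4 in 5 each. Cux2, Rorb or Pou3f2, which mark the upper layers, occurred together with at least 1 of the deep-layer genes Fezf2, Bcl11b, Tbr1, Foxp2 and Tle4 in 14 libraries, where independent detection gives 14.4. 5 libraries had genes of the upper set without the deep set, 5 had the reverse, and 1 had neither. Since each set was present in most libraries, most of the 25 had to hold both, so the 14 hardly tells exclusion from independence. Cux2 and Tbr1 met in 0 libraries (2.2 by independent detection), and Foxp2 and Tle4, both genes of layer 6, in 3 (1.4). Pou3f2 and Foxp2 met in 6 (3.1), Cux2 and Foxp2 in 5 (3.1), and Pou3f2 and Tle4 in 4 (2.2). Of the 15 pairs of an upper-set with a deep-set gene, 7 met more often than by independent detection and 8 less often. These overlaps were not tested.

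**Figure D3:**
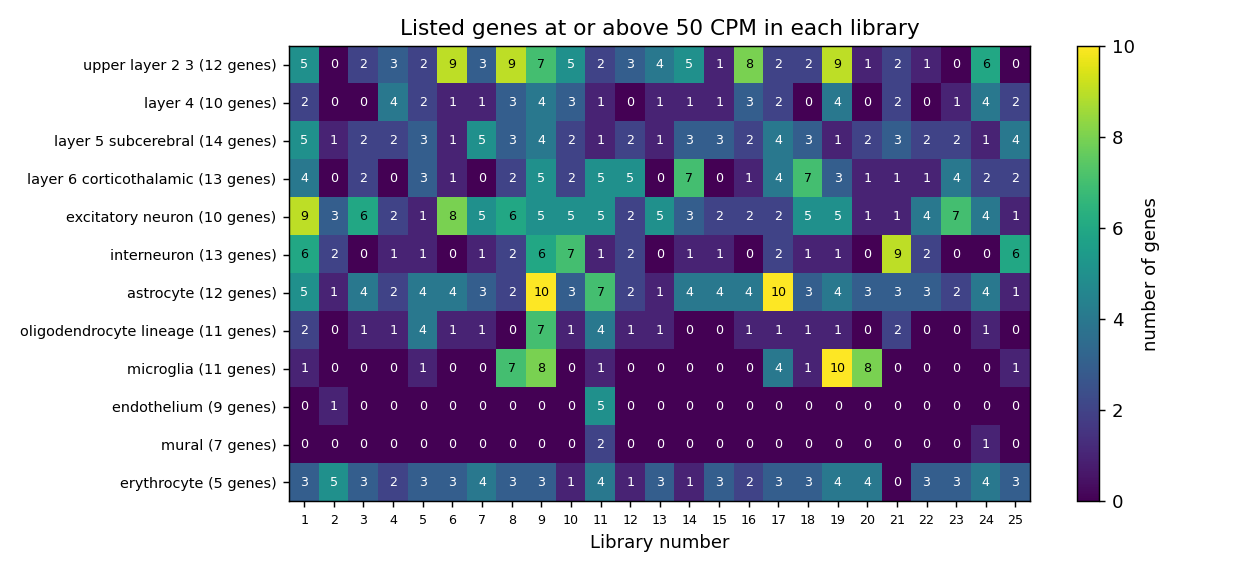
Number of listed genes at or above 50 CPM (cell values and color) for layer and cell type lists (rows, with the number of genes in each list) in the 25 libraries (columns). Library 21 shows 9 interneuron genes and 1 excitatory gene, and library 20 shows 8 microglia genes.

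The next comparison asks which genes differ between neurons that settled in the upper and in the lower cortical wall. Among 10389 genes tested, 2 were lower in the libraries named upper and 0 were higher, and both encode ribosomal RNA. mt-Rnr2, the mitochondrial large-subunit ribosomal RNA (ENSMUSG00000064339.1, chromosome M, 1094 to 2675, GRCm38), fell by 2.06 on the log2 scale (SE 0.32, limma adjusted p = 0.000949, lower in 3 of 3 pool sets). Its median was 6100 CPM in libraries named lower and 2387 CPM in those named upper. The call rested on library 17, named lower, which had 43894 CPM. Without that library the difference was -0.85 (limma adjusted p = 0.952). Rn18s-rs5, a copy of the 18S ribosomal RNA sequence (ENSMUSG00000106106.2), fell by 2.30 (SE 0.43, limma adjusted p = 0.0153, lower in 3 of 3). The annotation used holds no position for the latter. Reads of both can be shared with near-identical copies, so their levels are uncertain. The comparison used the 13 libraries whose names lie in 1 zone (6 lower, 3 middle and 4 upper). They were averaged within 3 pool sets: pool 1, pools 2 with 3, and pools 4 with 5. Several of these means held a single library. In pool 1 these were library 5 for lower and library 6 for upper. In pools 4 with 5 they were library 8 for middle and library 10 for upper. A sign in a pool set can therefore compare 1 library with 1 other. This choice of libraries was made after the columns had been compared. A library of 1 neuron cannot belong to both of its names, so "named upper" is a statement about names.

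Both calls ended without library 17 (0 genes, limma, and 450 at an unadjusted p below 0.05), although Rn18s-rs5 kept a difference of -2.16 there (limma adjusted p = 0.37). They also ended when any 1 of the 3 pool sets was left out (0 genes, limma), and without a term for the pool set (0 genes, limma adjusted p = 0.882 for both). At an unadjusted p below 0.05, 458 genes (4.41%) were found where 5% is expected by chance. The test as planned, edgeR on the 49 columns as named, called 0 genes, but it counts each pair of columns as 2 neurons. edgeR on the recovered reads called 6 genes with TMM scaling (2 higher, 4 lower) and 9 with RLE scaling, and DESeq2 called 408 (180 higher, 228 lower). DESeq2 did not call the ribosomal RNAs (adjusted p = 0.365 for mt-Rnr2 and 0.466 for Rn18s-rs5), while edgeR with TMM scaling called mt-Rnr2 (adjusted p = 0.0195) and not Rn18s-rs5 (adjusted p = 0.137). The 2 higher genes of edgeR with TMM scaling were the hemoglobin genes Hbb-bs (adjusted p = 1.76e-46) and Hba-a1 (3.43e-11). Library 11, named upper, had 165571 CPM of Hbb-bs, against 84.9 to 4400 CPM in the other 3 libraries named upper. Without library 11 limma called 6 genes (2 higher, 4 lower). The median log2 difference over all genes tested was 0.60, and each difference below is to be read against it. That median was 0.34 in edgeR with RLE scaling and 0.20 in DESeq2. In limma it was 0.27 without library 11 and 0.14, 1.46 and 0.25 without pool sets 1, 2 and 3. Read depth went partly with the name. Libraries named lower held 254182, 501246, 554839, 632018, 734065 and 3257485 reads. Those named upper held 639823, 967537, 3939266 and 6867017 reads. How far the general shift and the differences of low genes follow from depth was not tested.

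None of the layer genes named here passed the limma test. Pcp4, a calmodulin regulator of deep-layer neurons (ENSMUSG00000090223.1, chromosome 16, 96467606 to 96525793), had a log2 difference of -5.57 (SE 1.63, limma adjusted p = 0.944) with means of 509 CPM in libraries named lower and 154 CPM in those named upper. Single libraries crossed, with 607 CPM in library 11, named upper, and 1.3 CPM in library 23, named lower. On the log scale Foxp2 (-4.52, SE 2.24) and Bcl11b (-3.94, SE 2.05) were below 0, as were Pou3f2 (-2.86), Fezf2 (-1.67), Tbr1 (-1.32) and Rorb (-1.07), with limma adjusted p from 0.944 to 0.981. Foxp2 was lower in 3 of 3 pool sets and Bcl11b in 2 of 3. DESeq2 called Foxp2 (-6.43, adjusted p = 0.0106) and Pou3f2 (-6.56, adjusted p = 0.0343). Libraries with more reads of Gad1 and Gad2 than of Slc17a7 are called Gad-rich here. Without them Pou3f2 was above 0 in limma, so no direction is given for Pou3f2. Tle4 (1.49, SE 2.26, higher in 1 of 3 pool sets and lower in 1) and Cux2 (0.38, SE 1.81) were above 0. Mean CPM went the other way for 4 of these genes. Libraries named lower and upper averaged 16.8 and 23.6 CPM of Tbr1, 72.7 and 156 CPM of Rorb, 28.6 and 22.3 CPM of Tle4, and 96.6 and 45.5 CPM of Cux2, so no direction is given for them. Rorb turned to 1.02 in edgeR with TMM scaling, 0.64 with RLE scaling and 0.60 in DESeq2. Slc17a7 differed by 1.35 (SE 1.99) and Gad1 by 0.40 (SE 2.24).

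Among the genes with the smallest p that did not pass were Sh3bgrl (6.60, SE 1.83), Mtpn (3.70), Tubb2a (1.13), Fam49a (3.97), Msra (5.87), Snap25 (2.09) and Pcbp1 (4.15) on the higher side. On the lower side they were mt-Rnr1 (-2.35, SE 0.60), mt-Nd1 (-1.82, SE 0.48), mt-Cytb (-1.65), Plpp3 (-7.14) and Mrpl33 (-3.22). Their limma adjusted p lay between 0.711 and 0.944, and each had the same sign in 3 of 3 pool sets. Of these genes, DESeq2 called Sh3bgrl (adjusted p = 0.00129), Msra (0.0119) and Plpp3 (9.84e-07). The share of reads from the mitochondrial genome was 0.32 to 2.08% in 5 libraries named lower, 9.86% in the sixth, library 17, and 0.29 to 2.66% in those named upper.

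As groups, genes of deep-layer neurons had medians below 0 and passed 1 of 3 tests. Of the layer 5 list, 10 of 11 tested members were below 0 (median log2 difference -2.66), led by Pcp4, Etv1 (-4.75), Crym (-4.57) and Crim1 (-4.03). Of the layer 6 list, 7 of 9 were below 0 (median -3.13), with Crym, Foxp2, Sox5 (-3.26) and Rprm (-3.17). Both passed camera with its preset correlation (limma adjusted p = 2.14e-05 and 0.00169) and failed with an estimated correlation (adjusted p = 0.39 for both) and in fry (adjusted p = 0.416 for both). The 16 mitochondrial genes tested were each below 0 (median -1.28, camera adjusted p = 0.000336), as were 8 of 8 microglia genes (median -1.63, adjusted p = 0.000723, led by Aif1 at -5.34). The astrocyte list followed with 6 of 10 below 0 (median -1.06, adjusted p = 0.022, led by Apoe at -3.05). With an estimated correlation these 3 lists had adjusted p = 0.708. Adjusted over the list alone, 1 layer 5 gene, 0 layer 6 genes and 5 mitochondrial genes passed. Over all genes tested, mt-Rnr2 was the 1 member of these lists that did.

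Single libraries weighed on these lists. Without library 17 the mitochondrial median was -0.27 (camera adjusted p = 0.197), the astrocyte median 0.59 (adjusted p = 0.483), the layer 5 median -1.87 (adjusted p = 0.000331) and the layer 6 median -2.26 (adjusted p = 0.0102). The latter 2 had adjusted p = 0.485 with an estimated correlation and 0.756 in fry. 6 of the 13 libraries had more genes of interneurons, microglia or the oligodendrocyte lineage than of excitatory neurons at 50 CPM, by a rule set after the values were seen. Astrocyte genes did not enter the rule, so library 11 (7 astrocyte against 5 excitatory genes) and library 15 (4 against 2) were kept. The 6 are called led by another cell type here. In a fit without these 6 and without the pool set term, the layer 5 median was -1.85 (camera adjusted p = 0.00329) and the layer 6 median -1.37 (adjusted p = 0.307). With an estimated correlation the layer 5 list failed in that fit as well. The mitochondrial median was then 0.03, the microglia median -0.64 and the astrocyte median 0.80. The astrocyte median was 1.77 without pool set 2, and the layer 6 median was -0.70 without pool set 3 (camera adjusted p = 0.325). With all 49 columns under their names the layer 5 median was -1.55 (adjusted p = 0.09) and the layer 6 median -0.54 (adjusted p = 0.598). That fit counts each of the 24 pairs as 2 neurons. It also places 12 pairs in 2 zones, which draws differences toward 0, so it is not a test of robustness. The layer 6 list also failed camera without a filter on low counts (median -0.96, adjusted p = 0.0962) and without Gad-rich libraries (median -4.39, adjusted p = 0.096).

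The other 19 lists tested did not pass, although some did under single alternatives. The medians of 14 of these 19 took the other sign in at least 1 alternative, so no direction is given for them. Gad-rich is meant relative to Slc17a7, and library 11 counted as such with 1 of the 13 interneuron genes at 50 CPM. The layer 2 and 3 list passed camera without Gad-rich libraries (median 2.24, adjusted p = 0.0143), and the excitatory list without pool set 2 (median 3.55, adjusted p = 0.0156). With an estimated correlation these had adjusted p = 0.999 and 0.70, and in fry 0.945 and 0.61. Median log2 differences were 1.75 for layer 2 and 3 genes (8 of 11 above 0, camera adjusted p = 0.131, but a median of 1.01 without library 11), -0.50 for layer 4 genes, 1.01 for callosal genes (0.63 without library 11), 1.72 for excitatory neuron genes (9 of 10 above 0, adjusted p = 0.202, but a median of 0.25 without pool set 1) and -0.39 for interneuron genes. They were -0.44 for HCN channel genes (mean 0.37), -0.31 for leak and inward rectifier potassium channels, 0.62 for voltage-gated channels, -0.09 for glutamate receptors and 1.14 for GABA-A receptors. Axon guidance genes had a median of 1.32 (-0.22 without library 11), cadherins and contactins 0.02 (mean -0.12), genes of immature neurons 0.55, immediate early genes 0.36, cholesterol synthesis 1.56 and ribosomal proteins -0.20 (mean 0.04). Oligodendrocyte lineage genes stood at 0.45, endothelial genes at 1.55 and red cell genes at 2.03. Without library 11 the oligodendrocyte median was -0.65, the red cell median 0.08, and fewer than 3 endothelial genes were tested. For voltage-gated channels, cadherins and contactins, immediate early genes and the oligodendrocyte lineage the camera direction was down although the median was above 0, since camera sets a list against all other genes. Adjusted over the list alone, 1 immature neuron gene and 1 red cell gene passed, and 0 of each did over all genes tested. Subplate and mural lists had fewer than 3 genes tested.

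Between the middle and the lower zone, the lower means were those used above, library 17 included, so the 2 comparisons are not independent. mt-Rnr2 had a log2 difference of -2.46 in the libraries named middle (SE 0.38, limma adjusted p = 0.000628, lower in 2 of 2 pool sets). It was the 1 gene of 10389 that passed, and without library 17 its difference was -0.95 and limma called 0 genes (288 at an unadjusted p below 0.05). DESeq2 did not call it (adjusted p = 0.414). Of the libraries named middle, library 8 (7 microglia against 6 excitatory genes at 50 CPM) and library 21 (9 interneuron against 1) were led by another cell type. Cdh12, a cadherin (6.84, SE 2.30), Robo2, an axon guidance receptor (4.71, SE 1.80), Lrp8, a reelin receptor (7.0), Sgce (6.62), Tmem248 (6.87), B3glct (6.94), Copb1 (6.14) and Sh3bgrl (5.47) were higher without passing. Cck, which encodes cholecystokinin (-3.50, SE 1.06), mt-Nd1 (-2.28), mt-Cytb (-2.17), mt-Rnr1 (-2.51), Smarcb1 (-6.17), Ndufc2 (-2.86) and Smim14 (-5.11) were lower without passing. Limma adjusted p was 0.66 or more for these 15 genes. edgeR called 0 genes with TMM scaling and 2 with RLE scaling, DESeq2 called 447, and 303 genes had an unadjusted p below 0.05 in limma. Without pool set 2 or without pool set 3, the sets that hold a middle mean, limma called 0 genes.

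Between the upper and the middle zone, Malat1 was lower in the libraries named upper. This nuclear long noncoding RNA (ENSMUSG00000092341.2, chromosome 19, 5795690 to 5802672) fell by 1.91 on the log2 scale (SE 0.29, limma adjusted p = 0.000383, lower in 2 of 2 pool sets), with means of 28842 CPM in libraries named middle and 6141 CPM in those named upper. The call rested on library 7, named middle, which had 69717 CPM. Without that library the difference was -0.59 (limma adjusted p = 0.998). Library 7 also had the highest levels among the 25 libraries of Meg3 (14640 CPM), Snhg11 (9976 CPM) and Srrm2 (6086 CPM), 3 genes chosen after their values were seen. Malat1 was the 1 gene that passed, and DESeq2 did not call it (adjusted p = 0.648). Tmsb4x, which encodes an actin-binding thymosin, followed at -1.29 (SE 0.27, adjusted p = 0.085, and -1.69 with a limma adjusted p = 5.22e-16 without library 7). It had 1.45 without Gad-rich libraries. It was also above 0 with other zone limits and without libraries led by another cell type, so no direction is given for it. Among the libraries named middle it was highest in library 8 (34961 CPM) and library 21 (28265 CPM), both led by another cell type. Then came Arhgap42 (-8.28), Lpgat1 (-7.12), Brinp3 (-6.92), Slc24a2 (-7.03), Tcf12 (-7.04) and Zkscan2 (-5.99). Lpgat1 turned sign with other zone limits. Gap43 (1.66, SE 0.53), Smarcb1 (6.33), Emc9 (7.68), Smim14 (5.13), Uap1 (7.61), Mycl (8.04) and Nol12 (6.89) were higher, with a limma adjusted p of 1.0 for each. DESeq2 called some of these, among them Smarcb1 (adjusted p = 0.00053), Emc9 (0.000182), Smim14 (0.0231) and Uap1 (0.000269), and did not call Gap43 (0.716). edgeR called 3 genes with TMM scaling, Malat1 among them (adjusted p = 0.000421), and 6 with RLE scaling, DESeq2 called 550, and 338 genes had an unadjusted p below 0.05 in limma. Without pool set 2, which holds library 7, or without pool set 3, limma called 0 genes.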

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

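The tests in this part were chosen after the results had been seen. In 53 groups of 4 to 6 values, 7 held 1 value far from the rest, by the gap over the range. For genes this gap was taken on log2(CPM + 1). Chance gives about 1 in 20 for normally distributed values only. Where a single library has reads and the rest have 0, the gap is 1.0 whatever the level, so no excess over chance is drawn from the 7. Library 11, which held 21.8% red cell transcripts, was the lowest of the 4 libraries named upper for Sh3bgrl (128 CPM against 291.6 to 326.4, gap over range 0.879) and Tubb2a (809 CPM against 4787 to 6801, 0.835). Rorb was high in library 13 (613 CPM against 2.9 to 7.3, gap 0.850), Pou3f2 in library 6 (165 CPM, 0.931) and Bcl11b in library 10 (128.5 CPM against 0, 1.0). Tle4 was found in library 12 of the 6 named lower (172 CPM against 0, 1.0). Fezf2 had 0.2 CPM in library 6 and 0 in the other 3 libraries named upper (1.0), below the level of 3 reads. In the 12 libraries outside the comparisons, the highest share of hemoglobin and Alas2 reads was 69.0% of library 2, well above what a count of 0 allows.

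The 24 column pairs are the first pattern. Different neurons that resemble each other are argued against, since the second column held 0.652 to 0.822 of the reads of the first in each pair, whereas neighboring columns of different libraries had ratios from 0.189 to 9.381. A random division of 1 set of reads is argued against too, since the lowest ratio in a pair was 2.24 and Ccnd3 was lower in the second column in 24 of 24 pairs. Entry of 1 library under 2 names is consistent with the 0.173% of well-covered gene values that were 0 in the partner column. Which of the 2 names is right, if either, stays open, and no biological explanation was tested.

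The second pattern is high levels of transcripts of other cell types in single libraries. RNA of red blood cells may account for library 2, where 5 of 5 listed genes reached 50 CPM, with Hbb-bs at 484108 CPM. RNA of microglia may account for library 20, where 8 of 11 listed genes reached 50 CPM, against 3 astrocyte genes and 0 of the oligodendrocyte lineage, and where Tmsb4x stood at 178771 CPM. The microglia and red cell lists share no gene with the other lists. Whether such RNA came from the aspirated cell or from neighboring tissue stays open, and the dye label would select against both types.

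The third pattern is the lower level of the layer 5 list in libraries named upper (median -2.66). In 4 of the 10 splits of the 6 lower and upper means, the real one included, the median was as far from 0 (up to 3.49 in size), and 10 splits are too few for a share under 0.05. Libraries led by other cell types may contribute: without them the median was -1.85, and no value decides, because the list failed with an estimated correlation in both fits (adjusted p = 0.39 and 0.758). A difference with radial position stays open as well, untested while the names are in doubt. For the gene calls themselves, 2 of the 10 splits gave as many as the real 2 genes, the highest other split gave 7, and the splits are again too few.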

How the results depend on the processing

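The alternatives chosen after seeing the data were edgeR with TMM scaling on the libraries, the pseudocount of 10, the deeper column, hemoglobin, libraries led by another cell type, library 17, library 11, library 7, limma on the 49 columns as named, and for the gene lists the settings without a filter and without Gad-rich libraries. edgeR with TMM scaling on the 49 columns as named was the test as planned, and the main limma test replaced it after the table was opened. For upper against lower, middle against lower and upper against middle (main counts 2, 1 and 1), DESeq2 called 408, 447 and 550 genes, edgeR with TMM 6, 0 and 3, edgeR with RLE 9, 2 and 6, and the deeper column of each pair 4, 2 and 3. No filter on low counts gave 0, 0 and 0, as did leaving out libraries led by another cell type without the block, and the 49 columns as named in limma and edgeR. Leaving out library 17 gave 0, 0 and 1, library 11 gave 6, 2 and 4, and library 7 gave 5, 2 and 4. Leaving out libraries with Gad1 and Gad2 above Slc17a7 gave 0, 2 and 2, and other zone limits gave 0, 0 and 2. Without the replicate block 0, 0 and 1 genes were called, and 5 lists passed as before. A division at 0.45 gave 0 for upper against lower, reads in at least 10 libraries gave 1, and a pseudocount of 10 gave 0 for middle against lower. Without 1 pool set (a lone middle mean is left without set 2 or 3, and is assumed to vary like the others) the counts were 0 to 0, 0 to 1 and 0 to 2. Of the gene lists, 5 passed. With an estimated correlation and with 49 columns as named 0 passed, without a filter 3, without library 17 3, without Gad-rich libraries 2 and without libraries led by another cell type 2, and without 1 pool set 4 to 8. These were not always members of the 5. The layer 2 and 3 list passed without Gad-rich libraries (2.24), immediate early genes without libraries led by another type (-1.22), excitatory genes (3.55), glutamate receptors, cadherins with contactins and ribosomal proteins without pool set 2, interneuron (-0.93) and red cell (2.90) genes without pool set 3, and ribosomal proteins with a pseudocount of 10 (-0.25). The astrocyte median was -2.12 to 1.77 without 1 pool set, 0.59 without library 17 and 0.80 without libraries led by another type, where the mitochondrial median was 0.03. None of the 27 electrical alternatives turned a direction or passed the threshold. The sign-flip tests among them could not pass, since their smallest p is 0.0625 with 5 pools and higher with fewer. Without the pool as a block, a permutation test of the pool means could pass. It gave p = 0.0317 for Ih and 0.0397 for capacitance (adjusted p = 0.0596 for both). Leaving out 1 pool gave 7.95 to 12.85 pA, 6.70 to 14.21 pF and -6.33 to -4.19 mV. Named genes kept their direction and side of the threshold in 1021 of 1134 alternatives over the 3 comparisons, lost a call in 50, gained 1 in 34 and turned sign in 29. Most of the 56 named results had not passed in the main fit, so keeping their side mostly meant staying uncalled. Only the called genes, 2, 1 and 1 in the 3 comparisons, could lose a call, and the 50 losses fall on them. In upper against lower, without Gad-rich libraries, Pou3f2 had 2.65, Rorb 0.90, Cux2 -1.30 and Slc17a7 -1.04. In upper against middle, Tmsb4x had 1.45 without Gad-rich libraries, 2.01 with the other zones and 1.20 without libraries led by another type, and Lpgat1 had 0.36 with the other zones. In middle against lower, mt-Nd1 had 0.06 without libraries led by another type. In upper against lower, without 1 pool set Rorb ranged from -2.57 to 0.68, Cux2 from -1.54 to 2.12, Gad1 from -0.82 to 2.0 and Tle4 from -0.30 to 2.53. Gad1 had -0.96 without library 11. Tle4 had -1.18 without libraries led by another type. The division at 0.45 gave 0.83 for Tbr1 and -0.09 for Cux2, the other zones 0.62 for Rorb and -0.30 for Gad1, and a pseudocount of 10 gave -0.02 for Cux2. Rorb had 0.60 in DESeq2, 1.02 with TMM and 0.64 with RLE. With 49 columns as named, limma gave Cux2 -0.17 and Slc17a7 -0.49, and edgeR gave Tle4 -0.56, Cux2 -0.15, Bcl11b 0.69 and Slc17a7 -0.94. The cause was not tested, except that leaving out a pool set, Gad-rich libraries or libraries led by another type leaves fewer residual degrees of freedom, which leaving out library 17, 11 or 7 does not. The filter at 50000 reads and 1000 genes removed 0 columns, and slopes with their alternatives were not run. In the shallowest library a count of 0 leaves room for up to 11.8 CPM.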

Other observations

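The values by library were chosen after they were seen and carry no test, and the correlation tests below were written before their results were seen. Inflammatory genes were high in library 17, with 21904 CPM of the chemokine Ccl4, 5045 CPM of Ccl3 and 1796 CPM of Il1a. That library also had the highest mitochondrial share (9.86%) and 10 of 12 astrocyte genes at 50 CPM. Il1a reached 5093 CPM in library 20. Library 18 had 1009 CPM of Tle4, 707 CPM of Foxp2 and 281 CPM of Syt6, 3 genes of layer 6, and library 14 had 265, 154 and 144 CPM of the same genes. Rorb, a gene of layer 4, was highest in library 19 (1629 CPM) and library 8 (1110 CPM), both with 7 or more microglia genes at 50 CPM.

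Genes of excitability and activity were detected to different extents. Gria2 and Grin2b, which encode glutamate receptor subunits, reached 50 CPM in 23 of 25 libraries each, and the sodium channel gene Scn2a in 18. The immediate early gene Egr1 did so in 19 libraries and Fos in 12. Hmgcs1, of cholesterol synthesis, did so in 22.

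A hypothesis was that upper-layer and deep-layer genes exclude each other across libraries. 4 correlations were computed over 25 libraries, of mean log2(CPM + 1) of the layer 2 and 3 or layer 4 list with the layer 5 or layer 6 list, leaving shared genes out. Pearson's r was -0.16 and 0.15 for layers 2 and 3 with layers 5 and 6, and 0.15 and -0.11 for layer 4. Spearman's rho was -0.18, 0.31, 0.12 and -0.08. The smallest permutation p was 0.447 for Pearson's r (adjusted p = 0.592) and 0.139 for Spearman's rho (adjusted p = 0.555). Without the 2 libraries farthest from the median r was -0.11, 0.23, 0.16 and -0.18. With read depth removed r was -0.36, -0.02, 0.05 and -0.28, since each list rose with depth (r from 0.32 to 0.46). Neither exclusion nor joint expression was shown at this number of libraries, and the p-values treat libraries of unknown animals as independent.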
